A study of Mus musculus with 8 samples.

How the data were processed

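Total RNA of spleen cells from male mice was measured on Affymetrix mouse expression arrays, 1 array per sample. Per the labels' protocols, the spleens were teased through nylon screens, red cells were lysed with ammonium chloride, RNA was extracted with Trizol followed by a column, and biotin-labelled target was made with a one-cycle kit. The samples fell into 2 groups by their strain label, 4 of wild-type C57BL/6J and 4 of B6.SB-Yaa/J. Each sample came from 1 mouse except the third Yaa sample, which pooled the spleens of 2.

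The deposited values are MAS5 signals, an intensity per probe set on a linear scale, per the submitters' processing notes. The MAS5 version, its scaling target and any filter are not given in the sources used here. The table holds 45101 probe sets, 64 of them array controls, with signals from 0.0296 to 20431 and 0 missing values. The mean signal of an array, with the lowest and highest 2% of probe sets left out, ran from 106.9 in the third Yaa sample to 193.1 in the second wild-type sample, so the deposited arrays had not been brought to a common level. The number of arrays limits the precision of every comparison here.

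The choice of scaling, tests, gene lists and rule for naming genes was made before the data were examined. The deposited values were to be kept if the trimmed means of all arrays lay within 10% of their median, and since they did not, all arrays were quantile normalized. Values were then taken as log2(signal + 16), and fold changes are on that scale, which understates the change of dim probe sets. Controls and the probe sets at or below the median of mean log2 signal were left out, which left 22518. Yaa was compared with wild type with limma (version 3.58.1, R version 4.3.3), using lmFit and eBayes with a mean-variance trend, and p-values were adjusted by Benjamini-Hochberg over the tested probe sets with a threshold of 0.05. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

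Probe sets were named through the platform annotation, with symbols updated through Entrez gene IDs to those of GRCm38.p6, where 34754 of 35890 annotated probe sets matched. Of the probe sets other than controls, 34945 had 1 gene symbol, 932 had several and 9160 had none; genes were named only from the first kind. The assembly served for names and for the order of neighbouring genes. Where a gene had several tested probe sets, the one with the highest mean signal stood for it, which gave 10340 genes.

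The 28 fixed gene lists were the distal X segment known to be copied onto the Yaa chromosome, X genes beside it, Y-linked genes, response pathways, markers of spleen cell types and of neighbouring tissue, and unrelated abundant classes. Each list's mean per sample was compared by a two-sided exact permutation test over the 70 arrangements of 4 against 4, whose smallest p is 0.0286. The 27 lists with 3 or more tested genes were also tested with camera in limma, at a preset correlation of 0.01 and with an estimated one, and with fry. With an estimated correlation camera also uses the residual degrees of freedom of the fit, so its p can rise where the correlation does not. For the distal X list the estimated correlation was -0.039, yet the camera p rose from 1.6e-15 to 0.00015. Called genes were tested for their chromosomes with Fisher's exact test, two-sided.

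Named by the fixed rule are every tested gene of the distal X list, the 10 largest rises and 10 largest falls among genes past the threshold whose groups did not overlap, the genes with the smallest p up to a total of 20 where fewer passed, and up to 4 genes with the smallest p of each list. The second part of the rule gave 0 genes, so 20 came from the third. Genes outside the rule are named with a statement that they were chosen after their values were seen.

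The alternatives tried were other pseudocounts, filters and scalings, other variance models, limma array weights, a block for the replicate number, other thresholds and set tests, and each sample left out in turn. Dropping Yaa 2 and Yaa 3 together, taking the mean of the B cell list as a covariate, and leaving out single samples with the tested probe sets kept or with an estimated correlation in camera were added after seeing the data, as was that correlation with array weights or without Yaa 2 and Yaa 3. No 2 arrays held the same values, and correlations between arrays of log2 values ran from 0.81 to 0.99.

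The procedure was tested on simulated data for the comparison of 4 with 4, with 22518 probe sets of which 200 were changed. It recovered 4.48% of those changed 1.5-fold, 25.4% of those changed 2-fold and 81.8% of those changed 4-fold, with 5 false calls among 79. The simulated noise was independent between probe sets and of equal size in all arrays. The real arrays differed in spread and held genes that varied together, so these rates need not hold for them.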

Results

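Gene expression was compared between spleen cells of 8-week-old male mice with and without Yaa, a Y chromosome known to carry a copy of a distal segment of the X chromosome that includes Tlr7. The question was which genes differ between B6.SB-Yaa/J and C57BL/6J spleens. There were 4 samples per group. Beyond a test of whether called genes cluster on chromosomes, it was not analysed here whether the strains differ elsewhere in the genome. A difference between the groups therefore need not come from the Yaa chromosome. Samples are called wild type 1 to 4 and Yaa 1 to 4 by the replicate numbers in the labels. The trimmed mean signal of the arrays was 163 ± 21.1 (SD, n = 4) in wild type and 142 ± 26.6 (SD, n = 4) in Yaa (two-sided exact permutation p = 0.314, tested on log2 values). Yaa 2 and Yaa 3 stood apart from the other samples: the first principal component held 56.9% of the variance and placed Yaa 2 at 68.8 and Yaa 3 at -92.4, with the other 6 between them.

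Genes of the distal X segment were higher in Yaa. Over the 13 tested genes of the list, mean log2 signal was 8.10 ± 0.0084 (SD, n = 4) in wild type and 8.65 ± 0.066 (SD, n = 4) in Yaa, a rise of 0.55 (two-sided exact permutation p = 0.0286, the smallest the design allows, and 0.386 adjusted over the lists). From Trappc2, a trafficking subunit, to Hccs, which attaches haem to cytochrome c, 10 of 10 tested neighbours were higher, with a median log2 fold change of 0.76 (1.69-fold). Tlr7, a receptor for single-stranded RNA, had 0.91 ± 0.21 (SE), Tlr8 0.73 ± 0.17 (SE), Rab9, of late endosomes, 0.99 ± 0.12 (SE), Msl3 0.98 ± 0.14 (SE), and Hccs 1.01 ± 0.16 (SE). The smallest difference of the 10 was that of Tmsb4x, encoding an abundant actin-binding peptide, at 0.26 ± 0.07 (SE).

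The genes at both ends of the list did not share the difference. Gpm6b had a log2 fold change of -0.12 ± 0.21 (SE) and Ofd1 of 0.07 ± 0.16 (SE) on one side, and Mid1 had -0.24 ± 0.24 (SE) on the other. Mid1 had -0.58 ± 0.21 (SE) with array weights and -0.0092 without Yaa 1. The sign of Gpm6b turned with median-centred arrays and that of Ofd1 with the values as deposited. The 17 tested X genes beside the segment differed by -0.005 (exact permutation p = 0.971), among them Sat1 at 0.24, Syap1 at 0.20, Txlng at -0.16 and Ap1s2 at 0.17, of which Syap1 and Ap1s2 turned sign with the values as deposited. Sat1 and Syap1 fell to 0.085 and 0.070 without Yaa 2. Txlng moved to -0.10 without Yaa 4 and Ap1s2 fell to 0.086 without wild type 1. Segment minus neighbours differed by 0.56 between the groups (exact permutation p = 0.0286).

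No segment gene passed limma's test over all probe sets, where 0 had an adjusted p under 0.05 and 9 an unadjusted p under 0.05; 8 of 13 passed when adjusted over the list alone, and with limma array weights 6 passed over all probe sets, and 9 higher and 1 lower, Mid1, adjusted over the list alone. camera gave the list an adjusted p of 2.2e-14, and adjusted p = 0.0041 with an estimated correlation, which was 0.010 to 0.032 with single samples left out. With the values as deposited, the difference of the list mean was 0.37 (exact permutation p = 0.0857); this scaling moved the median of all probe sets by -0.20, and the list less each array's median then differed by 0.59 (exact permutation p = 0.0286).

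**Figure D1:**
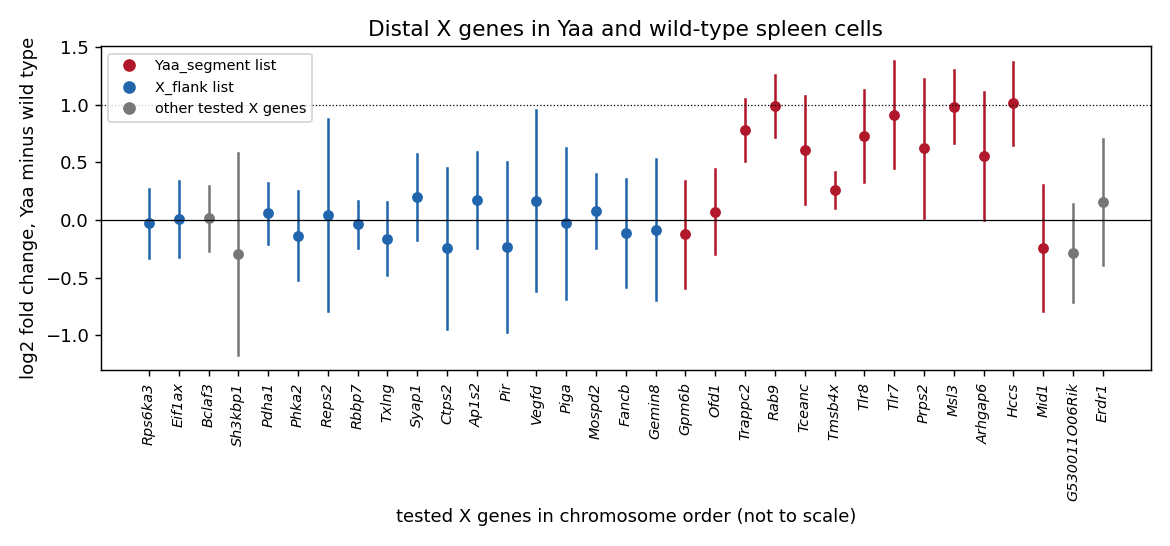
Log2 fold change (Yaa minus wild type, n = 4 each) of tested X genes in chromosome order, with 95% intervals as bars and a dotted line at 2-fold; genes of the segment list are red, its neighbours blue and other X genes grey. The 10 genes from Trappc2 to Hccs lie at 0.26 to 1.01, and Gpm6b, Ofd1 and Mid1 lie at -0.24 to 0.07.

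Across the array, 1 of 22518 tested probe sets rose past the threshold and 0 fell. It belonged to Casp9, which encodes the initiator caspase of the mitochondrial death pathway, and is named because it is the only call. Its log2 signal was 4.27 ± 0.07 (SD, n = 4) in wild type and 6.81 ± 0.30 (SD, n = 4) in Yaa, a log2 fold change of 2.54 ± 0.18 (SE; limma adjusted p = 0.0041). Wild type lay near the floor of 4 that the added 16 sets, so the size of the change depends on that constant, and with log2(signal + 64) it was 1.25 (limma adjusted p = 0.021). Both other tested Casp9 probe sets had log2 fold changes of 0.25 ± 0.16 and 0.18 ± 0.21 (SE). At an unadjusted p under 0.05 limma listed 668 higher and 397 lower probe sets, where 1126 were expected by chance, and 4.10% of probe sets did not overlap between the groups, where chance gives 2.86%.

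The genes with the next smallest p did not pass limma's test without array weights. Apart from genes of the segment they included Slfn4 (log2 fold change 2.24), Cd14, a co-receptor for lipopolysaccharide (2.44), Fpr2, a formyl peptide receptor of phagocytes (1.56), Trem1 (1.38), Sgms2 (1.69), Arg2 (1.56), Ccr1 (1.13), Ifitm3 (0.64), Map3k12 (1.04) and Ptp4a2 (0.52) on the higher side, and Taf15 (-0.89) and mitochondrial ND5 (-0.41) on the lower. Map3k12, Taf15 and Ptp4a2 each had another tested probe set with a difference of the opposite sign.

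With limma array weights, which gave Yaa 2 and Yaa 3 weights of 0.22 each, 102 probe sets rose and 41 fell, the Casp9 probe set among them. In that fit Cd14 rose by 2.25 ± 0.25 (SE) and Slfn4 by 1.96 ± 0.18 (SE) on the log2 scale (limma adjusted p = 0.0036 and 0.0032), and the other genes with the next smallest p, chosen by the same p without weights, passed as well (limma adjusted p 0.0036 to 0.046). Without Yaa 2 alone 30 probe sets passed, without Yaa 4 alone 10, and without Yaa 2 and Yaa 3 together 105. Without Yaa 1 or Yaa 3 alone limma called 0 (1024 and 1563 at an unadjusted p under 0.05). The Casp9 probe set fell below the filter in every fit that left out a Yaa sample, so it is not among the 30, 10 or 105. With the tested probe sets kept it passed without any single sample.

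Markers of neutrophils had higher means in Yaa, but not in every sample. All 14 tested genes had higher means, and the list's mean log2 signal was 8.14 ± 0.34 (SD, n = 4) in wild type and 9.64 ± 1.03 (SD, n = 4) in Yaa (exact permutation p = 0.0571, and 0.386 adjusted over the lists). S100a8 and S100a9, the calprotectin subunits, had log2 fold changes of 1.31 and 1.47, and the secreted proteases Mmp8 and Mmp9 of 1.94 and 1.27. In Yaa 2 the list stood at 8.26, below wild type 1 at 8.61, and without Yaa 2 the difference was 1.96 (exact permutation p = 0.0286), and without Yaa 1 or Yaa 3 it was 1.17 or 1.34 (exact permutation p = 0.0571 each). limma called 0 of the 14 over all probe sets, with 10 at an unadjusted p under 0.05 and 8 adjusted over the list alone. With array weights it called 12. camera gave an adjusted p of 3.6e-17, but with an estimated correlation the adjusted p was 0.262, and fry gave 0.236.

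The list of monocyte and macrophage markers was higher by 0.54, at 8.87 ± 0.026 (SD, n = 4) in wild type and 9.41 ± 0.40 (SD, n = 4) in Yaa (exact permutation p = 0.0286, and 0.386 adjusted over the lists). The lysozyme genes Lyz2 and Lyz1 had 0.98 and 0.69, and the Fc receptor gene Fcgr4 had 0.84. limma called 0 of 18 over all probe sets, with 7 at an unadjusted p under 0.05 and 6 adjusted over the list alone, and with array weights it called 4. camera gave 2.1e-09, and adjusted p = 0.268 with an estimated correlation. Mast cell, basophil and eosinophil markers differed by 0.71 (exact permutation p = 0.114), with Mcpt8 at 1.13, Cpa3 at 0.62, Epx at 0.87 and Gata2 at 0.37. camera gave 6.3e-05, and adjusted p = 0.262 with an estimated correlation. limma called 0 of these 6 over all probe sets, with 3 at an unadjusted p under 0.05, and 1, Mcpt8, adjusted over the list alone, which was also the 1 call with array weights. Without Yaa 2 the difference of the mast cell list was 0.97 (exact permutation p = 0.0286), and without Yaa 1 or Yaa 3 it was 0.52 or 0.57 (exact permutation p = 0.200 each). Epx fell to 0.38 without Yaa 1. The monocyte list was highest in Yaa 3, at 9.93, and differed by 0.36 without that sample (exact permutation p = 0.0286) and by 0.29 without Yaa 2 and Yaa 3 (exact permutation p = 0.0667). Without any 1 of the wild-type samples it differed by 0.53 to 0.55 (exact permutation p = 0.0571).

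**Figure D2:**
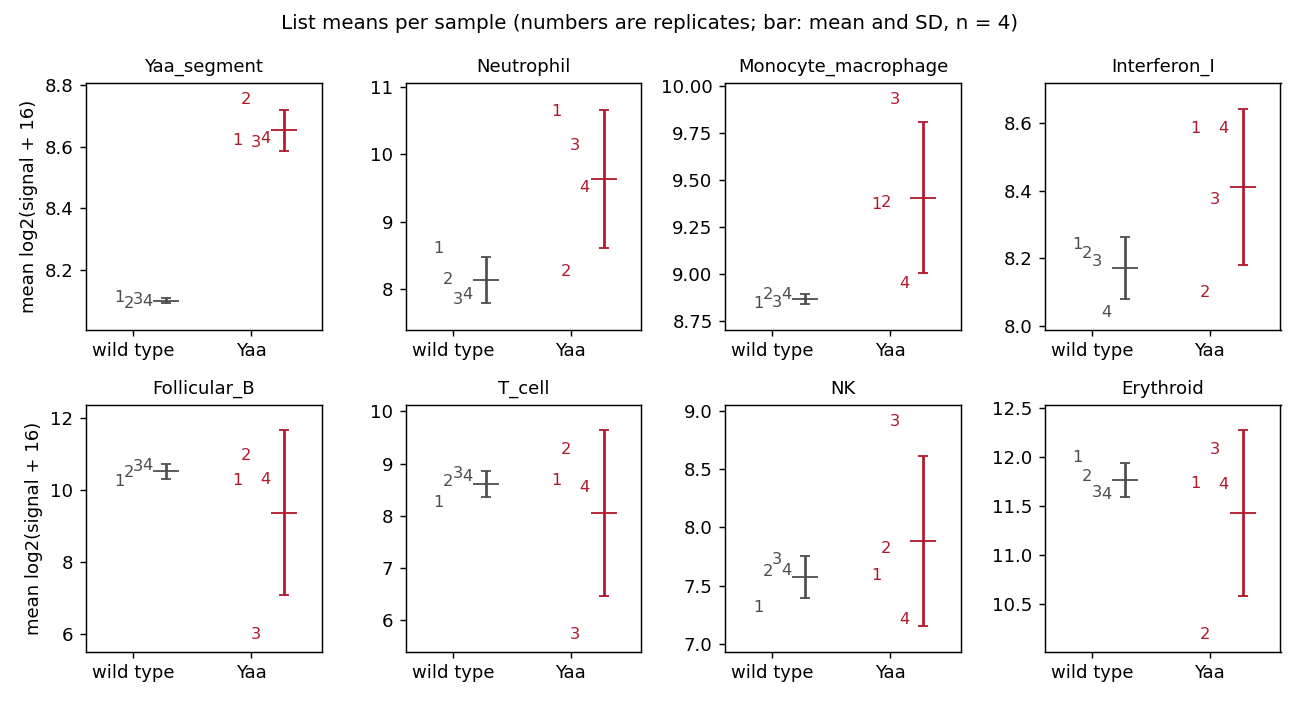
Mean log2(signal + 16) of 8 gene lists in each sample, with numbers for the replicates and bars for the group mean and SD (n = 4). In Follicular_B, Yaa 3 lies at 5.97 and the other Yaa samples at 10.26 to 10.96, and in Erythroid, Yaa 2 lies at 10.18.

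Genes of the type I interferon response differed by 0.24 on average, with 16 of 21 higher (exact permutation p = 0.114); without Yaa 2 the difference was 0.34 (exact permutation p = 0.0286), and without Yaa 1 or Yaa 4 it was 0.18 (exact permutation p = 0.200 each). Rtp4 had 0.99, Oas1a, an RNA-sensing synthetase, 0.58, Oasl2 0.56, which fell to 0.33 without Yaa 1, and Bst2, which tethers virions, 0.55. limma called 0 over all probe sets, with 4 at an unadjusted p under 0.05 and 2 adjusted over the list alone; with array weights it called 2, Oas1a and Rtp4. camera gave 6.3e-05, and adjusted p = 0.262 with an estimated correlation. Genes of the Toll-like receptor and NF-kB response differed by 0.35 (exact permutation p = 0.114; camera adjusted p = 6.0e-06, and adjusted p = 0.431 with an estimated correlation), with the chemokines Cxcl2 at 1.44, Cxcl10 at 0.81 and Ccl3 at 0.51, and Nfkbiz at 0.58. The list stood at 9.24 in Yaa 2 and at 8.44 to 8.72 in the other Yaa samples. The difference was 0.19 without Yaa 2 and 0.46 without Yaa 4 (exact permutation p = 0.257 and 0.0286), and 0.14 without Yaa 2 and Yaa 3 (exact permutation p = 0.533). limma called 0 of these 20 over all probe sets, with 6 at an unadjusted p under 0.05, and 0 adjusted over the list alone. The signalling components of TLR7 itself differed by 0.02 (exact permutation p = 0.914), by -0.10 without Yaa 2 and by 0.12 without Yaa 3, with Myd88 at 0.22, Tlr9 at 0.28, Tirap at 0.32 and Slc15a4 at -0.33. The sign of Myd88 turned with the values as deposited. Without Yaa 3, Tlr9 moved to 0.14, Myd88 to 0.11 and Slc15a4 to -0.19, and without Yaa 2 Tirap moved to 0.21.

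Handling-sensitive genes had a mean difference of 0.27 but a median of 0.04, with 12 higher and 8 lower (exact permutation p = 0.0571; camera adjusted p = 0.011, and adjusted p = 0.262 with an estimated correlation). camera no longer called the list without wild type 1 or without Yaa 2 (adjusted p 0.073 and 0.327), and the difference was 0.34 without Yaa 3 and 0.22 without Yaa 2 (exact permutation p = 0.0286 and 0.0571). The 4 with the smallest p were heat shock genes, the inducible Hspa1a at 2.15 and Hspa1b at 1.84, Hsph1 at 0.92 and Hsp90aa1 at 0.35. limma called 0 of the 20 over all probe sets, with 5 at an unadjusted p under 0.05, and 4 adjusted over the list alone; with array weights it called 3, Hspa1a, Hspa1b and Hsph1.

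Lymphocyte markers varied most through Yaa 3. B cell markers stood at 10.50 ± 0.20 (SD, n = 4) in wild type and 9.37 ± 2.29 (SD, n = 4) in Yaa (exact permutation p = 0.543). In Yaa 3, the pool of 2 spleens, the list stood at 5.97. Cd79b, of the B cell receptor, had a log2 fold change of -1.24, Cd22 of -1.16, Cd37 of -1.12 and Pax5 of -0.40. T cell markers differed by -0.56 (exact permutation p = 0.771), with Ccr7 at -1.13, Cd3e at -0.93, Cd5 at -0.68 and Lef1 at -0.59. MHC class II genes differed by -0.61 (exact permutation p = 0.429), with H2-DMa at -0.59, H2-Aa at -0.56, Ciita at -0.47 and H2-Eb1 at -0.43. camera called all 3 lower (adjusted p 0.00067, 0.027 and 0.0041), and none with an estimated correlation (adjusted p = 0.711, 0.720 and 0.711). Without Yaa 3 the mean differences were -0.007, 0.22 and -0.04, camera no longer called the B cell and MHC class II lists, and it called the T cell list higher (adjusted p = 0.0037, and adjusted p = 0.570 with an estimated correlation). Without Yaa 2 they were -1.67, -0.96 and -0.95 (exact permutation p = 0.0857, 0.200 and 0.0857). Without Yaa 2 and Yaa 3 together they were -0.24, -0.003 and -0.27 (exact permutation p = 0.267, 1 and 0.333). camera then again called the B cell and MHC class II lists lower (adjusted p 0.00036 each, and adjusted p = 0.515 each with an estimated correlation). It also did so with array weights (adjusted p 0.014 and 0.0013, and adjusted p = 0.813 and 0.697 with an estimated correlation). The T cell call was lost in both of these fits. It was also lost without wild type 3 or wild type 4 and with log2(signal + 64) (adjusted p 0.076, 0.066 and 0.052), and with the values as deposited camera called neither the T cell nor the MHC class II list (adjusted p 0.456 and 0.132). With the mean of the B cell list as a covariate, the lower calls of all 3 lists were lost. This fit cannot test them. The B cell list was adjusted for its own mean, so its call had to go. The T cell and MHC class II lists were also lowest in Yaa 3, at 5.72 and 9.03. The B cell mean varied mostly through that sample. In 2 of 19 settings, the fit without Yaa 3 among them, camera called the T cell list higher.

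NK cell markers differed by 0.31 (exact permutation p = 0.600) and stood at 8.90 in Yaa 3; Nkg7 had 0.52, Gzmb 0.62, Eomes 0.49 and Ccl5 0.44. Markers of splenic macrophages differed by 0.29 (exact permutation p = 0.771) and stood at 9.89 in Yaa 3, with the complement genes C1qa at 0.85 and C1qb at 0.45, Timd4 at 0.43 and Nr1h3 at 0.29. camera called both higher (adjusted p 0.011 and 0.0067), with adjusted p = 0.720 for both with an estimated correlation. Without Yaa 3 the differences were -0.04 and -0.05 and neither was called. The NK difference was 0.53 without Yaa 4 and the splenic macrophage difference 0.44 without Yaa 2 (exact permutation p = 0.114 and 0.200). The NK call was also lost without wild type 1 or without Yaa 2 (adjusted p 0.096 and 0.097). limma listed 1 gene of each at an unadjusted p under 0.05 and called 0, over all probe sets or adjusted over the list alone.

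Erythroid markers differed by -0.34 (exact permutation p = 0.771), with 17 of 17 lower, among them Bpgm at -0.58, Alas2, of haem synthesis, at -0.40, Hbb-b2 at -0.76 and Trim10 at -0.44. Cell cycle genes differed by -0.28 (exact permutation p = 0.83), with Aurkb at -0.53, Plk1 at -0.51, Ube2c at -0.50 and Cdk1 at -0.47. camera called both lower (adjusted p 0.0060 and 0.013), with adjusted p = 0.720 and 0.726 with an estimated correlation. Both lists were lowest in Yaa 2, at 10.18 and 9.47; without it the differences were 0.08 and 0.11 and neither was called. Without Yaa 3 they were -0.55 and -0.51 (exact permutation p = 0.229 and 0.343). The cell cycle call was also lost without wild type 1 (adjusted p 0.120), and both had an adjusted p of 0.054 with the values as deposited and 0.052 with median-centred arrays.

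The remaining lists were not called by camera without array weights. With them it called megakaryocytes lower and activated T cells and plasma cells higher (adjusted p 0.0054, 0.037 and 0.043). With array weights and an estimated correlation it called none of them (adjusted p = 0.451, 0.697 and 0.697). It also called these 3 without Yaa 2 and Yaa 3 together (adjusted p 0.0015, 0.0044 and 0.0016). With an estimated correlation it again called none (adjusted p = 0.302, 0.515 and 0.515). Mean log2 differences were -0.22 for marginal zone B cells (Myof -0.54, Cd9 0.36), 0.29 for germinal centre B cells (Basp1 0.84), -0.24 for plasma cells (Slpi 0.98, Xbp1 0.48), 0.09 for activated T cells (Cd44 0.53, Tbx21 0.71), -0.03 for dendritic cells (Siglech 0.31), -0.14 for megakaryocytes, 0.14 for stroma and endothelium (Acta2 0.61, Kdr 0.53), -0.12 for pancreas, 0.01 for ribosomal proteins and 0.002 for respiration genes (Cox5a 0.20). Exact permutation p-values ran from 0.229 to 1 over these lists. Among megakaryocyte markers Thbs1 had 1.32, against -0.66 for Vwf and -0.59 for Ppbp. limma called 0 megakaryocyte genes over all probe sets, with 3 at an unadjusted p under 0.05, and 1, Thbs1, adjusted over the list alone, which was also the 1 call with array weights. The plasma cell list had a mean of -0.24 but a median of 0.09 and the dendritic list a mean of -0.03 but a median of 0.07, and camera's direction was up for both; the stroma list had a mean of 0.14 but a median of 0.02. Single samples moved several of these means. Without Yaa 3 they were 0.17 for marginal zone B cells, 0.39 for plasma cells, 0.42 for germinal centre B cells, 0.35 for activated T cells and -0.29 for megakaryocytes (exact permutation p = 0.286, 0.0286, 0.0857, 0.0857 and 0.0286), and -0.07 for stroma and -0.43 for pancreas (exact permutation p = 0.429 and 0.0571). Without Yaa 2 they were -0.43 for marginal zone B cells, -0.52 for plasma cells, 0.15 for germinal centre B cells, -0.09 for activated T cells, -0.08 for megakaryocytes, -0.20 for dendritic cells and 0.04 for pancreas (exact permutation p from 0.143 to 0.943). Without wild type 1 they were 0.19 for germinal centre B cells and -0.0056 for activated T cells (exact permutation p = 0.457 and 0.943). Without Yaa 3, camera called activated T cells, plasma cells, germinal centre and marginal zone B cells higher and megakaryocytes lower at the preset correlation (adjusted p 4.5e-05, 6.0e-05, 0.018, 0.015 and 0.00074), but none with an estimated correlation (adjusted p = 0.315 for the first 3, 0.502 and 0.287). Without wild type 2, wild type 4 or Yaa 1, camera called megakaryocytes lower, activated T cells higher and stroma higher in turn (adjusted p 0.040, 0.033 and 0.037), and none of them with an estimated correlation. Y-linked genes differed by -0.16 (exact permutation p = 0.143), by -0.22 without wild type 4 (exact permutation p = 0.0286) and by -0.11 without wild type 1 (exact permutation p = 0.257), with the histone demethylase gene Kdm5d at -0.66, Eif2s3y at -0.23 and Uty at 0.41. limma called 0 of these 3 over all probe sets, with 1 at an unadjusted p under 0.05, and 1, Kdm5d, adjusted over the list alone. The 2 tested adipose genes, Scd1 and Fabp4, had -0.98 and 0.16 and were too few for camera; their mean differed by -0.41 (exact permutation p = 0.229), by -0.60 without Yaa 2 (exact permutation p = 0.0286), by -0.13 without Yaa 3 (exact permutation p = 0.400) and by -0.28 without both (exact permutation p = 0.200).

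In all, camera placed 14 of 27 lists past the threshold, 9 higher and 5 lower, and 1 of them, the distal X segment, held with an estimated correlation. With array weights 12 lists passed: the T cell, NK cell, splenic macrophage, erythroid and cell cycle lists no longer did, and the megakaryocyte, activated T cell and plasma cell lists did. With weights and an estimated correlation only the distal X segment passed (adjusted p = 0.0053). No exact permutation p was under 0.386 when adjusted over the lists. A list that alone reached the smallest p of 0.0286 could not pass, so this adjustment cannot tell whether a single list differs. No gene of the 10340 was called at its representative probe set, with 501 at an unadjusted p under 0.05 in limma, so no chromosome could be tested at that threshold. At an unadjusted p under 0.01 the X chromosome held 7 of 135 genes, with 306 of the 10323 tested genes lying on it (Fisher's exact test, adjusted p = 0.653), and no chromosome passed. Without Yaa 2, chromosome 11 held 7 of 20 called genes against 892 of 10353 tested (Fisher's exact test, adjusted p = 0.0206). It held 9 of 53 without Yaa 2 and Yaa 3 together and 10 of 80 with array weights, and passed in neither (Fisher's exact test, adjusted p = 0.559 and 1).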

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

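The tests of the low lymphocyte transcripts in Yaa 3 were chosen after the result was seen; the counts over other splits of the samples were planned before. A sample is listed here where its distance to the nearest sample of its group was a large part of that group's range, by Dixon's criterion for 4 samples. Of 318 groups of values examined 27 met it, and chance gives about 5%.

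Yaa 3 accounted for 10 of the 27. The gap as a share of the range was 0.860 for the mean of the B cell list, 0.831 for plasma cells, 0.894 for megakaryocytes and 0.832 for stroma and endothelium. Among genes it was 0.954 for Pax5, 0.876 for Cd79b, 0.844 for Cd22, 0.832 for C1qb, 0.896 for Gata2 and 0.872 for Sparc. The B cell and plasma cell values were lower in Yaa 3 than in the other Yaa samples; those of megakaryocytes, stroma, C1qb, Gata2 and Sparc were higher.

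Over 28 markers of B and T cells, the median of Yaa 3 was -3.74 log2 units from the mean of the other 3 Yaa samples, and 27 of the 28 lay more than 1 log2 unit below that mean. The dimness of the array does not account for this, since with the values as deposited and the shift of all probe sets taken off the median was -3.64. The Gapdh 3' over 5' signal of Yaa 3 was 0.773, within the range of the other 7 arrays, which goes against degraded RNA, although its actin ratio of 1.38 was the highest of the 8. If only 1 of the 2 pooled spleens lacked lymphocytes, an even pool would have kept the median within 1 log2 unit, so -3.74 also goes against that. The segment list of Yaa 3 stood 0.50 above the highest wild-type sample; a low lymphocyte content of both spleens, from the mice or from the preparation of the cells, stays open and was not tested.

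Yaa 2 accounted for 5. The share was 0.901 for the segment list, which was highest in Yaa 2, 0.850 for Ptp4a2, 0.919 for Bpgm, 0.862 for Alas2 and 0.862 for Aurkb; Ptp4a2 was higher and the last 3 lower there. Wild type 1 accounted for 8, with 0.871 for the Toll-like receptor and NF-kB list, 0.894 for TLR7 signalling, 0.944 for plasma cells, 0.914 for Bst2, 0.916 for Xbp1, 0.844 for Eomes, 0.920 for S100a8 and 0.980 for H2-Aa, of which S100a8 was higher in that sample and the rest lower. The other 4 were wild type 4, with 0.906 for megakaryocytes and 0.932 for Ccl3, wild type 2, with 0.835 for Sparc, and Yaa 1, with 0.848 for Oasl2.

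The real split stood out from the others by its count of probe sets with array weights, but not by its count of lists. So few splits cannot exclude chance, and the other splits mix both groups, which widens the spread of genes that differ by group. The weighted count also leaned on Yaa 1 and Yaa 4, with weights of 2.23 and 1.13 against 0.22 each for Yaa 2 and Yaa 3. With array weights, 1 of the 35 splits of the 8 samples into 4 and 4, the real one, called as many as its 143 probe sets, and the highest other called 1. Without weights again 1 split, the real one, called as many as its 1 probe set, and the highest other called 0, but a single call is a thin basis, since 1065 probe sets had an unadjusted p under 0.05 in limma where chance gives 1126. For lists past the threshold in camera, 8 of the 35 splits gave as many as the real 14, and the highest other, which put Yaa 3 with wild type 1, wild type 3 and wild type 4, gave 18.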

How the results depend on the processing

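The count of 1 probe set stayed at 1 with log2(signal + 64), no filter, the values as deposited, and both other variance models. It was 0 with log2(signal + 1) and 0 above the 70th percentile, where the Casp9 probe set fell below the filter (1031 and 609 at an unadjusted p under 0.05 in limma), 7 with median-centred arrays, 10 at an adjusted p under 0.10 and 143 with array weights. Chosen after seeing the data, leaving out Yaa 2 and Yaa 3 gave 105, and the B cell list as a covariate 14. Leaving out single samples gave 0 to 30. With the tested probe sets kept, a choice also made after seeing the data, it gave 2 without Yaa 1, 31 without Yaa 2, 11 without Yaa 4 and 1 otherwise, and Casp9 stayed past the threshold in all 8 fits at a log2 fold change of 2.45 to 2.61 (limma adjusted p 0.0037 to 0.043). With log2(signal + 64) its change was 1.25 (limma adjusted p = 0.021).

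Nothing in the labels says that same-numbered samples were handled together, and the correlations of their deviations were -0.01, 0.02, -0.37 and -0.13. These correlations cannot exclude shared handling, since Yaa 2 and Yaa 3 stood apart from the other samples. The replicate block gave 0 calls (736 at an unadjusted p under 0.05 in limma), 14 lists, and a segment difference of 0.55 with an exact permutation p of 0.125, the smallest that 4 pairs allow. The segment difference was 0.37 with the values as deposited, which moved all genes, and 0.52 without Yaa 2 and Yaa 3 (exact permutation p = 0.0667, the smallest those samples allow); single samples left out gave 0.52 to 0.56. Lists past the threshold numbered 12 with array weights, 1 with an estimated correlation, 1 with fry, and 10 to 15 with single samples left out. Chosen after seeing the data, an estimated correlation gave 1 with each single sample left out, with array weights, and without Yaa 2 and Yaa 3. Chromosomes past the threshold numbered 0 to 1 with single samples left out; in 15 of 21 fits, and without the segment genes, no gene was called and none was tested.

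Of 2518 values of named genes under alternatives, 2412 kept their direction and side of the threshold, 72 passed only there and 1 no longer passed (Casp9 in the replicate block); 33 changed sign, none of them past the threshold, and the cause was not tested. With the values as deposited these were Ofd1 -0.13, Syap1 -0.033, Ap1s2 -0.050, Myd88 -0.0069, Fabp4 -0.016, Rps6 -0.039 and Sdhc -0.047; with median-centred arrays Gpm6b 0.0067, Rpl7 0.11 and Rps9 0.11; with array weights Cdh5 -0.076 and Fabp4 -0.069. With single samples left out, 46 of 128 named genes fell under 50% of their change or turned, 28 of them without Yaa 3 and 13 without Yaa 2. Ofd1 ranged from -0.045 (without wild type 4) to 0.16. Turning without Yaa 2, Mki67 ranged from -0.41 to 0.060, Trim10 from -0.67 to 0.011 and Cela1 from -0.52 to 0.27. Turning without Yaa 3, Gpm6b ranged from -0.22 to 0.047, Cd3e from -1.45 to 0.069, Cd5 from -1.09 to 0.12, Lef1 from -1.05 to 0.095, Sparc from -0.14 to 0.66 and Fabp4 from -0.21 to 0.33. Without both Yaa 2 and Yaa 3 they were Gzmb -0.11, Eomes -0.013, Cdh5 -0.062, Sparc -0.047 and Fabp4 -0.13, and with the B cell covariate Gpm6b 0.054, Cd3e 0.083, Cd5 0.13, Lef1 0.13, Sparc -0.13 and Fabp4 -0.20. Probe sets near the floor of the signal have understated changes.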

Other observations

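The tests of explanations in this part were chosen after the result was seen, as were the genes named here outside the fixed lists; the fits with array weights, other scalings and log2(signal + 64) were planned before. Some probe sets split the Yaa samples among themselves. Igtp and Irgm2, interferon-inducible GTPase genes, were at 10.21, 9.97 and 10.37 and at 9.04, 9.03 and 9.13 log2 in Yaa 1, Yaa 3 and Yaa 4, but at 8.89 and 6.82 in Yaa 2, where wild type lay at 8.56 to 8.83 and 6.68 to 7.17; both passed limma's test with array weights (adjusted p = 0.0036 each), which counted Yaa 2 little. Of the H2-D1 probe sets, 1 was at 11.49 in Yaa 1 and 11.22 in Yaa 4 and at 5.79 to 7.71 in the other 6 samples. Ifi213 was at 5.85 in Yaa 3 and 5.81 in Yaa 4, against 8.35 to 9.50 elsewhere, and 1 of 2 Ifi209 probe sets was at 7.12 and 6.36 there, against 9.66 to 10.22. The other Ifi209 probe set was at 6.94 in Yaa 3 but at 8.91 in Yaa 4, against 9.41 to 9.94, so the low values of Yaa 3 at these genes need not differ in origin from its low lymphocyte transcripts. Of the Pdxdc1 probe sets, 1 was at 7.38, 8.45 and 8.03 in Yaa 1, Yaa 3 and Yaa 4, and at 4.19 to 5.45 in Yaa 2 and wild type. The 3 other tested Pdxdc1 probe sets were lower in those 3 samples than in the rest. The 4 other H2-D1 probe sets did not set Yaa 1 and Yaa 4 apart in that way. With array weights the split H2-D1 probe set passed (log2 fold change 3.83, limma adjusted p = 0.020). So did the first Pdxdc1 probe set and 1 of the others (2.51 and -0.92, limma adjusted p = 0.022 and 0.032). The weighted calls thus include probe sets on which the Yaa samples split. Such splits raise the doubt whether the Yaa mice shared 1 genetic background with each other and with wild type. It was not tested directly, and it bears on every difference between the groups. The test of the chromosomes of called genes, in which 1 chromosome passed without Yaa 2, bears on this doubt. That fit left out the Yaa sample that Igtp and Irgm2 set apart, so its result need not be a separate observation. The test also counts each gene as independent of its neighbours. It cannot settle the doubt, since it compares no strain sequences.

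Other probe sets separated all 4 Yaa samples from wild type in 1 direction while further probe sets of the same gene did not. Kif5b had log2 fold changes of -1.16 ± 0.15 and -1.38 ± 0.22 (SE) at a pair of probe sets and -0.25 to 0.15 at 4 others. Zfp24 had 1.48 ± 0.18 (SE) at 1 probe set and -0.91 to -0.02 at 5 others, and the one at -0.91 also separated the groups, the other way. None passed limma's test without array weights. With them the pair of Kif5b probe sets and the Zfp24 probe set at 1.48 passed (limma adjusted p = 0.0036, 0.0128 and 0.0036).

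In Yaa 3, Ms4a1, the gene of CD20, was at 4.08 log2 and Cd3d at 4.40, against 11.65 to 12.55 and 9.38 to 10.77 in the other 7 samples, while Gzma, of cytotoxic cells, was at 11.58 with Yaa 2 next. In Yaa 2, Slc4a1, the band 3 gene of red cells, was at 11.98 against 13.26 to 13.61. Tfrc, the transferrin receptor gene, was at 10.03 against 11.72 to 12.09 at 1 probe set. The Tfrc probe set with the highest mean signal showed a smaller drop, at 11.87 in Yaa 2 against 12.69 to 13.10.

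Neutrophil markers were higher in Yaa 1, Yaa 3 and Yaa 4. Yaa 3 alone does not carry the difference, which was 1.34 without it. With the erythroid mean as a covariate the difference was 1.87 ± 0.29 (SE). The erythroid mean varied mostly through Yaa 2, and leaving out Yaa 2 alone gave a similar 1.96. The covariate fit therefore cannot decide whether the red-cell content of the suspensions plays a part. A lower share of lymphocytes, raising every other cell type alike, is contradicted for Yaa 1, Yaa 2 and Yaa 4 as a set: NK, splenic macrophage and megakaryocyte markers differed by -0.13 there (95% interval -0.31 to 0.05), against 1.34 for neutrophil markers. The gap between neutrophil markers and the mean of these and erythroid markers was 1.57 (exact permutation p = 0.0286), and with red-cell markers left out 1.46 (exact permutation p = 0.0571), where Yaa 2, whose neutrophil markers were not raised, lay at 0.62, below wild type 1. Lists outside this test also rose without Yaa 3, monocyte and macrophage markers by 0.36 and mast cell, basophil and eosinophil markers by 0.57. B cell and T cell markers then differed by -0.007 and 0.22. For Yaa 3 a lower share stays open, since NK and splenic macrophage markers also stood above wild type there, by 1.33 and 1.31. Megakaryocyte markers stood above wild type there only by 0.31. The Yaa genotype, and housing, shipment or infection of the mice, also stay open and were not tested.

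The Casp9 call rested on 1 of 3 tested probe sets. A change of the whole gene by that size is contradicted by the others, whose 95% intervals reach at most 0.66. Scaling of the arrays left at least 2.42, but wild type lay near the floor of the signal, and with log2(signal + 64) the change was 1.25. A sequence that differs under the probes could give such a pattern, as could a transcript that only these probes read; neither was tested, since probe and strain sequences were not used here.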
